A study of Mus musculus with 12 samples.

How the data were processed

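RNA from 12 samples of BV2 mouse microglia was sequenced, with 4 libraries each for Control, OGD and Acacetin. The labels describe total RNA taken up in TRIzol, treated with DNase, made into stranded mRNA libraries and read as pairs on a NovaSeq instrument. The submitters' processing notes name bcl2fastq, HISAT2, DESeq2 and the mouse build GRCm39, without versions and without saying which step used which. The read counter, the annotation release and the strand setting were not given in the sources used here. The labels do not say whether the 4 libraries of a group came from separate cultures. If they were technical repeats, every p-value measures only the spread between these samples.

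The deposited count table holds raw read counts per gene, as whole numbers, for 24934 genes with at least 1 read in some library. The authors' deposited FPKM table (fragments scaled by gene length and library depth) holds 24728 genes and leaves out those with 1 to 4 reads in all. The ratio of FPKM to count between libraries was the same for all genes, so 1 depth per library and 1 length per gene had been used. All 12 columns of each table matched a library by name, with 0 columns unmatched. Gene symbols, identifiers, chromosomes and biotypes were taken from the deposited table, which gives no start or end positions. Chromosomes are therefore given without positions.

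Library depth was the sum of counts per library and ran from 16427886 to 32693066 reads. Reads without molecular identifiers are not independent molecules, so depth limits only the counting error of a value. CPM values, which are read counts scaled to a library of common size, were computed with TMM-scaled library sizes, except where they are given per all reads.

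Choices stated in this and the next paragraph were made before the data were examined. Genes were tested with edgeR 4.0.16 in R 4.3.3. The function filterByExpr by group (minimum count 10, minimum total 15) kept 13249 genes. All 12 libraries entered 1 quasi-likelihood fit with a mean per group and TMM scaling, and the 3 comparisons were contrasts of that fit. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05 with no limit on the fold change. Log2 fold changes are given with their standard error (SE). Group means are given with the standard deviation (SD) and n = 4 libraries per group.

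A set of 39 gene lists with 724 entries and 703 distinct symbols was written from general knowledge, and 617 of the symbols were among the tested genes. Camera (limma 3.58.1) compared each of the 33 lists with at least 5 tested genes with all other genes, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. The p-values were adjusted over the 33 lists. Camera with an estimated correlation, and fry, which tests only whether a list's genes move 1 way on balance, were run beside it. The mean log2 CPM of each list was also compared between groups of 4 libraries by an exact permutation test, whose smallest two-sided p is 0.0286.

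Genes are named by a fixed rule. For each comparison it takes the 6 largest rises and the 6 largest falls among called genes with a mean of at least 2 CPM over the 12 libraries, no overlap between the groups, and a symbol that is not a model or clone name. It takes the 3 members with the smallest p from the inflammatory NF-kB and hypoxia lists, and from up to 8 other lists with the smallest camera p and at least 3 called members. It always takes Tnf, Il1b, Il6, Ccl2, Nos2, Ptgs2, Arg1, Vegfa and Hmox1. It also takes up to 5 genes per direction called in OGD against Control and called the opposite way in Acacetin against OGD, of which there were 0. Any other gene named was chosen after its values were seen.

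The comparisons share libraries, and this alone gives their fold changes a correlation. Its size was taken from 20 simulated sets of negative binomial counts with no difference between groups. The shared group was also split so that different libraries entered each comparison, and each of the 6 splits of the OGD libraries was kept as an alternative. For each pair of groups the libraries were regrouped in all 35 ways into 4 and 4, with the remaining group kept, and the counts of called genes and lists were taken again.

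The alternatives planned before the data were examined were DESeq2 1.42.0 (Wald test), its size factors in edgeR, no filter on low counts, a mean of at least 1 CPM, an absolute log2 fold change of at least 1, only the 8 libraries compared, the replicate numbers as a block, counts thinned to the smallest library, a prior count of 5, limma on log2 FPKM with 1 or 0.1 added, camera with an estimated correlation, fry, and leaving out each library of the groups compared. Alternatives chosen after the data were seen removed a trend with gene length (lowess, span 0.5), left out rRNA genes with Lars2, left out OGD 2 and 3, left out Acacetin 1 and 3, left out Acacetin 1 and 3 with OGD 4, or left out each library of the group outside the comparison. FPKM, no filter and thinned counts for named genes, and camera on FPKM, were also added then. Figures were drawn with matplotlib 3.10.9.

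The procedure was tested on simulated data in which 50 genes per size were changed. At a 1.5-fold change edgeR recovered 10% of them in OGD against Control, 12% in Acacetin against OGD and 2% in Acacetin against Control. At a 2-fold change it recovered 50%, 40% and 58%, and at a 4-fold change 96%, 94% and 90%. Unchanged genes gave 8, 4 and 4 calls. Camera called a list raised 1.5-fold (1 of 1) and 0 of the others. The simulated genes were drawn independently, so this cannot show how often lists of correlated genes would be called. Alternative splicing was not analysed here, since the tables used hold 1 value per gene.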

Results

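Gene expression was measured by RNA sequencing in BV2 cells, an established mouse microglial line. The 12 libraries formed 3 groups of 4. Control cells carry no treatment in the labels. OGD cells went through oxygen and glucose deprivation followed by re-oxygenation, a culture model of stroke. Acacetin cells received 10 µM acacetin, a plant flavone. The treatment label of the last group does not itself state OGD, but the design text of the series describes deprivation and re-oxygenation followed by acacetin, and the group was read that way.

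Library depth was 26177150, 24760961, 26088751 and 28674548 counted reads in Control 1 to 4, and 31811719, 24826738, 16427886 and 24945006 in OGD 1 to 4. It was 24734868, 32693066, 27556244 and 26245750 in Acacetin 1 to 4. Reads of 18S ribosomal RNA made up 13.1% of OGD 2 and 21.3% of OGD 3, and from 0.137% to 1.86% of the other 10 libraries. The slope of a library's log2 expression on log2 gene length ran from -0.264 in Acacetin 1 to 0.398 in Acacetin 3, so coverage of long genes was most uneven among the Acacetin libraries. The myeloid gene Lyz2 (lysozyme) averaged 1713 CPM (read counts scaled to a common library size) over all libraries. The first principal component held 41.3% of the variance and the second 32.0%. Errors given after a log2 fold change are SE, and errors after a mean CPM are SD with n = 4 libraries. Chromosomes are those of GRCm39.

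**Figure D1:**
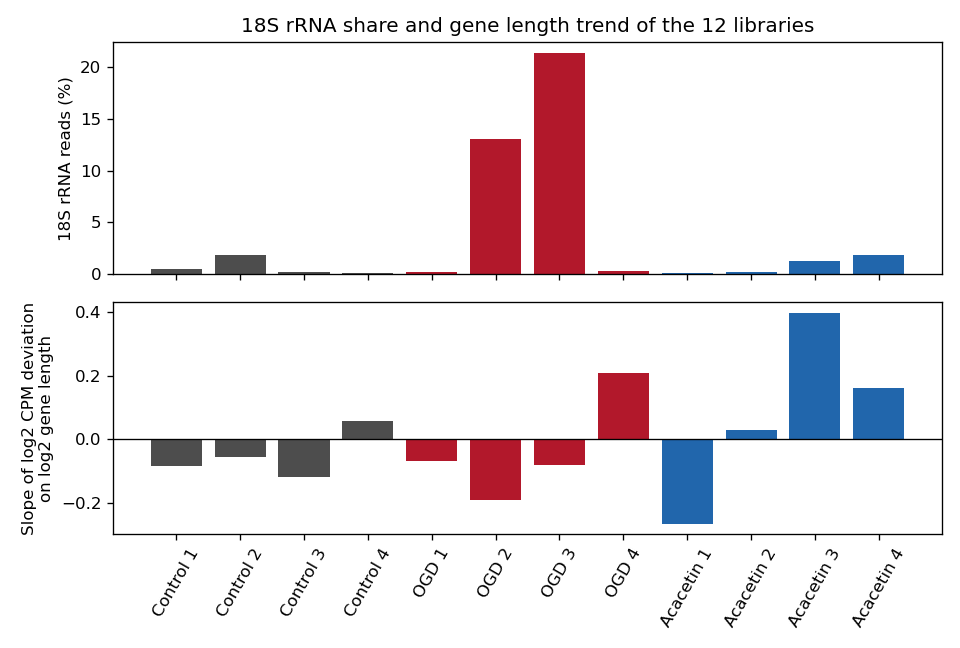
Bars give, for each of the 12 libraries, the percent of reads from 18S rRNA and the slope of log2 CPM deviation on log2 gene length. OGD 2 and OGD 3 held 13.1% and 21.3% 18S reads, and the slopes were most apart between Acacetin 1 (-0.264) and Acacetin 3 (0.398).

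OGD against Control asked which genes changed with deprivation and re-oxygenation. Srsf6 (ENSMUSG00000016921.15, chromosome 2), which encodes a splicing regulator, rose from 45.0 ± 8.52 CPM in Control to 159 ± 12.5 CPM in OGD. Mat2a (ENSMUSG00000053907.11, chromosome 6), whose enzyme makes S-adenosylmethionine, rose from 7.36 ± 3.66 to 65.6 ± 19.6 CPM. The cytokine gene Il1b (ENSMUSG00000027398.14, chromosome 2) rose from 16.4 ± 4.95 to 40.6 ± 5.73 CPM, with a log2 fold change of 1.31 ± 0.19 and an adjusted p of 0.000295. The chemokine gene Ccl3 (ENSMUSG00000000982.6, chromosome 11) moved the other way, from 4111 ± 974 to 1073 ± 39.3 CPM, and so did Lcn2 (ENSMUSG00000026822.15, chromosome 2), which encodes an iron-scavenging acute-phase protein, from 391 ± 22.1 to 107 ± 21 CPM.

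Of 13249 genes tested by edgeR, 3813 were called in OGD against Control, 2148 higher and 1665 lower, and 9436 were not. The 2 groups did not overlap in 36.0% of tested genes, where chance gives 2.86%. At least 2-fold changes numbered 719 higher and 813 lower. Protein-coding genes gave 1906 rises and 1512 falls among 11479 tested, and lncRNA genes 184 and 114 among 1039. The shares called were 29.8% and 28.7%, close to the 28.8% of all tested genes. The share of higher calls was 56.3%. It was 51.9% with the size factors of DESeq2 in edgeR (2048 higher and 1897 lower), and 32.2% with limma on the deposited FPKM values (911 higher and 1920 lower), where test, unit and scaling all differ. On FPKM with 0.1 added the median of all genes lay at -0.11. Leaving out OGD 2 and 3, the libraries rich in 18S rRNA, left 2024 calls, of which 1970 were among the 3813.

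The 6 largest rises named by the rule included Apol9a (ENSMUSG00000057346.13, chromosome 15), an interferon-inducible apolipoprotein L gene, from 2.89 ± 1.17 to 28.7 ± 8.63 CPM (log2 fold change 3.30 ± 0.31, adjusted p = 3.11e-05), and its neighbour Apol9b (ENSMUSG00000068246.7), from 2.84 ± 1.09 to 23.7 ± 6.35 CPM. These paralogs are similar in sequence, and how their reads were divided is uncertain. Mat2a rose by 3.16 ± 0.37 on the log2 scale (adjusted p = 0.000117). The kinase gene Tssk6 (ENSMUSG00000047654.7, chromosome 8), known from testis, rose by 3.20 ± 0.44 from 0.422 ± 0.260 CPM, and the monoamine transporter gene Slc18a1 (ENSMUSG00000036330.13, chromosome 8) by 3.07 ± 0.40 from 0.376 ± 0.162 CPM. Snora73b (ENSMUSG00000065353.3, chromosome 4), a small nucleolar RNA without a poly(A) tail, rose by 3.08 ± 0.54 and reached 7.59 and 13.8 CPM in OGD 2 and OGD 3, the libraries rich in 18S rRNA.

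Among the falls, Tox2 (ENSMUSG00000074607.12, chromosome 2), a lymphoid transcription factor gene, went from 6.33 ± 1.90 to 0.540 ± 0.279 CPM (log2 fold change -3.51 ± 0.38, adjusted p = 7.53e-05). Cbr2 (ENSMUSG00000025150.11, chromosome 11), a carbonyl reductase gene, fell by 3.18 on the log2 scale, and Ecel1 (ENSMUSG00000026247.14, chromosome 1), which encodes a membrane peptidase, fell by 3.12. The glucose transporter gene Slc2a8 (ENSMUSG00000026791.15, chromosome 2) went from 43.2 ± 5.13 to 6.67 ± 2.19 CPM. Lta (ENSMUSG00000024402.6, chromosome 17), the gene of the cytokine lymphotoxin alpha, went from 49.4 ± 4.49 to 8.06 ± 2.18 CPM with an adjusted p of 4.80e-05. Creg2 (ENSMUSG00000050967.6, chromosome 1), a secreted glycoprotein gene, fell by 2.58 on the log2 scale.

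The inflammatory NF-kB list held 3 called rises and 9 called falls among 27 tested genes, and the same 3 and 9 when adjusted over the list alone, with 15 not called. Nfkbid (ENSMUSG00000036931.16, chromosome 7), a nuclear inhibitor of NF-kB, rose from 24.3 ± 5.41 to 72.5 ± 6.73 CPM (log2 fold change 1.58 ± 0.18, adjusted p = 0.000117), and the adhesion molecule gene Icam1 rose by 0.71. Ccl3 had a log2 fold change of -1.94 ± 0.20 (adjusted p = 5.98e-05) and Lcn2 of -1.87 ± 0.21 (adjusted p = 0.000102). Of the other falls, the chemokine genes Cxcl2 and Ccl4 had log2 fold changes of -0.97 and -0.93, and the NF-kB subunit genes Relb and Nfkb2 of -0.71 and -0.60. The mean of the list was -0.34 and its median -0.39. The camera adjusted p was 0.0935 (0.687 with an estimated correlation), so camera did not separate the list from other genes. Fry, which does not compare it with other genes, gave an adjusted p of 0.0223. The list means per library did not overlap between the groups (exact permutation p = 0.0286, or 0.0629 after adjustment over the lists).

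Nos2 (ENSMUSG00000020826.10, chromosome 11), which encodes inducible nitric oxide synthase, went from 193 ± 25.9 to 79.2 ± 33.7 CPM (adjusted p = 0.00471, but 0.0564 without OGD 2 and 3). The monocyte chemokine gene Ccl2 (ENSMUSG00000035385.6, chromosome 11) had a log2 fold change of -0.55 ± 0.17 and an adjusted p of 0.0234. Its call was lost without Control 2 (0.0730), OGD 1 (0.0502), OGD 2 (0.0512) or OGD 4 (0.0547), and with the length trend removed (0.0614), while the log2 fold change stayed between -0.47 and -0.56. Ptgs2 (ENSMUSG00000032487.9, chromosome 1), the gene of cyclooxygenase 2, had -1.71 ± 0.55 and an adjusted p of 0.0302. The log2 fold change and adjusted p were -1.69 and 0.0611 without Control 2, -1.73 and 0.0613 without OGD 1, -1.50 and 0.0885 without OGD 2, -1.64 and 0.0987 without OGD 3, and -1.31 and 0.136 without Control 4. They were -0.87 and 0.0829 with limma on FPKM. Tnf (ENSMUSG00000024401.15, chromosome 17), the gene of tumour necrosis factor, averaged 592 ± 53.6 CPM in Control and 452 ± 50.4 CPM in OGD and was not called (adjusted p = 0.106), but DESeq2 gave 0.0240, limma on FPKM 0.0232 and edgeR without Control 4 0.0359.

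Il6 (ENSMUSG00000025746.12, chromosome 5), another cytokine gene, averaged 2.10 ± 0.302 CPM in Control and 2.34 ± 0.584 CPM in OGD (adjusted p = 0.784), and its log2 fold change was 0.15 on counts, -0.00 on FPKM and -0.04 without OGD 2. Arg1 (ENSMUSG00000019987.10, chromosome 10), an arginase gene used as a marker of alternative activation, had -1.14 ± 0.78 (adjusted p = 0.302). Without OGD 1, the library with the highest Arg1 level of its group, that value was -2.87 with an adjusted p of 0.0103. The other OGD libraries stood at 0.0999 to 0.552 CPM, so it rests on few reads. The growth factor gene Vegfa (ENSMUSG00000023951.19, chromosome 17) had 0.08 ± 0.16 (adjusted p = 0.757) on counts and -0.04 on FPKM. Heme oxygenase gene Hmox1 (ENSMUSG00000005413.9, chromosome 8) had -0.41 ± 0.20 (adjusted p = 0.137), with 0.0493 by DESeq2.

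Hypoxia-induced genes moved in both directions. Car9 (ENSMUSG00000028463.15, chromosome 4), the carbonic anhydrase gene used as a marker of low oxygen, fell from 3.60 ± 0.746 to 0.725 ± 0.206 CPM (log2 fold change -2.28 ± 0.35, adjusted p = 0.000450). Ak4 (ENSMUSG00000028527.19, chromosome 4), a mitochondrial adenylate kinase gene, rose from 18.4 ± 1.12 to 32.9 ± 3.47 CPM (0.84 ± 0.14, adjusted p = 0.000633, but 0.0857 with limma on FPKM). Ddit4 (ENSMUSG00000020108.5, chromosome 10), an inhibitor of mTOR signalling, had -1.51 ± 0.34 (adjusted p = 0.00469) and -1.13 with 0.0679 without OGD 2 and 3. Of 21 tested genes 2 rose and 6 fell, also when adjusted over the list alone. The other called members were Hk2 (0.58) and the falls of Ankrd37 (-0.98), Ero1a (-0.70) and Ndrg1 (-0.46), among others. The list median was 0.02 and the mean -0.19, with opposite signs, and the camera adjusted p was 0.530.

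Camera called 8 of the 33 lists in OGD against Control, 7 higher and 1 lower. Splicing factors had 21 rises, 1 fall and 18 genes not called among 40 tested (23 and 1 adjusted over the list alone), with a mean of 0.57 and an adjusted p of 0.000103 (0.641 with an estimated correlation). Srsf6 had a log2 fold change of 1.82 ± 0.15 (adjusted p = 2.64e-05), Srsf2 (ENSMUSG00000034120.19, chromosome 11) of 1.26 ± 0.13, and Srsf3 (ENSMUSG00000071172.14, chromosome 17) of 1.43 ± 0.17. The single fall was Cirbp (-1.01), an RNA-binding protein known for its response to cold.

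Endoplasmic reticulum chaperone genes gave 8 rises and 0 falls among 18 (10 rises adjusted over the list alone), with a mean of 0.56 and an adjusted p of 0.000745 (adjusted p = 0.255 with an estimated correlation). Dnajb11 (ENSMUSG00000004460.18, chromosome 16), a co-chaperone of BiP, rose from 44.6 ± 4.24 to 103 ± 8.37 CPM (adjusted p = 4.80e-05). Syvn1 (ENSMUSG00000024807.19, chromosome 19), a ubiquitin ligase of protein degradation, and the chaperone gene Hyou1 (ENSMUSG00000032115.15, chromosome 9) rose by 0.97 and 0.92 on the log2 scale. Cytosolic heat shock genes gave 6 rises among 14, also when adjusted over the list alone, and all 14 were higher on average (mean 0.59, adjusted p = 0.0154, and adjusted p = 0.413 with an estimated correlation). Hspa8 (ENSMUSG00000015656.18, chromosome 9) had 0.69 ± 0.17 with an adjusted p of 0.00808, and 0.0739 without OGD 2 and 3. Dnaja1 (ENSMUSG00000028410.14, chromosome 4) had 1.08 ± 0.30 with 0.0154, and 0.0503 without Control 1, 0.0553 without OGD 3 and 0.170 with limma on FPKM. Stip1 (ENSMUSG00000024966.10, chromosome 19) had 0.39 ± 0.12 with 0.0237, and 0.0637 without Control 1, 0.0667 without Control 2, 0.0747 without OGD 2 and 0.435 with limma on FPKM.

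DNA replication genes gave 11 rises among 23 (12 adjusted over the list alone, adjusted p = 0.00102, and adjusted p = 0.621 with an estimated correlation), among them Fen1 (ENSMUSG00000024742.16, chromosome 19), a flap endonuclease gene, from 76.0 ± 14.3 to 195 ± 25.9 CPM. The ribonucleotide reductase gene Rrm2 (ENSMUSG00000020649.12, chromosome 12) rose by 1.08 ± 0.14 and Uhrf1 (ENSMUSG00000001228.15, chromosome 17), which maintains DNA methylation, by 0.93 ± 0.14. Ribosome biogenesis genes gave 11 rises and 1 fall among 22, also when adjusted over the list alone (adjusted p = 0.00129, and adjusted p = 0.533 with an estimated correlation). Rrs1 (ENSMUSG00000061024.9, chromosome 1) rose by 1.27 ± 0.13, the RNA polymerase I gene Polr1b (ENSMUSG00000027395.16, chromosome 2) by 1.00 ± 0.15 and Nop2 (ENSMUSG00000038279.11, chromosome 6) by 0.83 ± 0.14, while Noc2l fell by 0.45. Cytosolic ribosomal protein genes were lower in 25 of 25, with a mean of -0.33, an adjusted p of 0.0114 (adjusted p = 0.726 with an estimated correlation) and 0 genes called singly.

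Interferon response genes gave 10 rises and 1 fall among 31 (12 and 2 adjusted over the list alone), with a mean of 0.49 and an adjusted p of 0.0154 (adjusted p = 0.687 with an estimated correlation). Oas2 (ENSMUSG00000032690.17, chromosome 5), an antiviral sensor gene, rose from 8.34 ± 1.07 to 22.9 ± 5.94 CPM (log2 fold change 1.46 ± 0.18, adjusted p = 0.000174). Rtp4 (ENSMUSG00000033355.7, chromosome 16) rose by 1.38 ± 0.20, and Usp18 (ENSMUSG00000030107.11, chromosome 6), which removes ISG15 from proteins, from 73.1 ± 17.7 to 169 ± 29.5 CPM. Ifi27l2a was the called fall (-1.10). Toll-like receptor signalling genes gave 9 rises and 1 fall among 17, also when adjusted over the list alone (mean 0.66, adjusted p = 0.0262, and adjusted p = 0.641 with an estimated correlation). The adaptor gene Myd88 (ENSMUSG00000032508.9, chromosome 9) rose from 57.5 ± 12.8 to 173 ± 21.2 CPM, the receptor gene Tlr2 (ENSMUSG00000027995.11, chromosome 3) rose by 1.25 ± 0.16 and the adaptor gene Tirap (ENSMUSG00000032041.16, chromosome 9) by 1.15 ± 0.23 (adjusted p = 0.00239, and 0.0937 with limma on FPKM). The adaptor gene Ticam1 had -0.54.

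Without OGD 4 the mean of the interferon list was 0.36 (adjusted p = 0.0584), that of the Toll-like receptor list 0.56 (0.0682) and that of the ribosomal proteins -0.20 (0.130). By the exact permutation test on list means per library (two-sided, n = 4) the p was 0.0571 for the interferon and ribosomal protein lists, whose groups overlapped, and 0.0286 for the other 6 lists (0.0629 after adjustment over the lists). With an estimated correlation 0 of the 8 lists, and 0 of all 33, were called. Fry, which tests only whether a list's genes move, called 15 lists, 7 of them among the 8. Its value for the ribosomal proteins was 0.198.

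NRF2-dependent antioxidant genes gave 8 rises and 1 fall among 21, also when adjusted over the list alone, while the list as a whole had a camera adjusted p of 0.0690. Srxn1 (ENSMUSG00000032802.9, chromosome 2), which repairs peroxiredoxins, rose by 1.49 ± 0.17 (adjusted p = 0.000116). The thioredoxin reductase gene Txnrd1 (ENSMUSG00000020250.12, chromosome 10) rose by 1.06 ± 0.17, and the quinone reductase gene Nqo1 (ENSMUSG00000003849.9, chromosome 8) from 2.73 ± 0.233 to 8.39 ± 3.23 CPM. The ferritin gene Fth1 was the fall (-0.77).

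**Figure D2:**
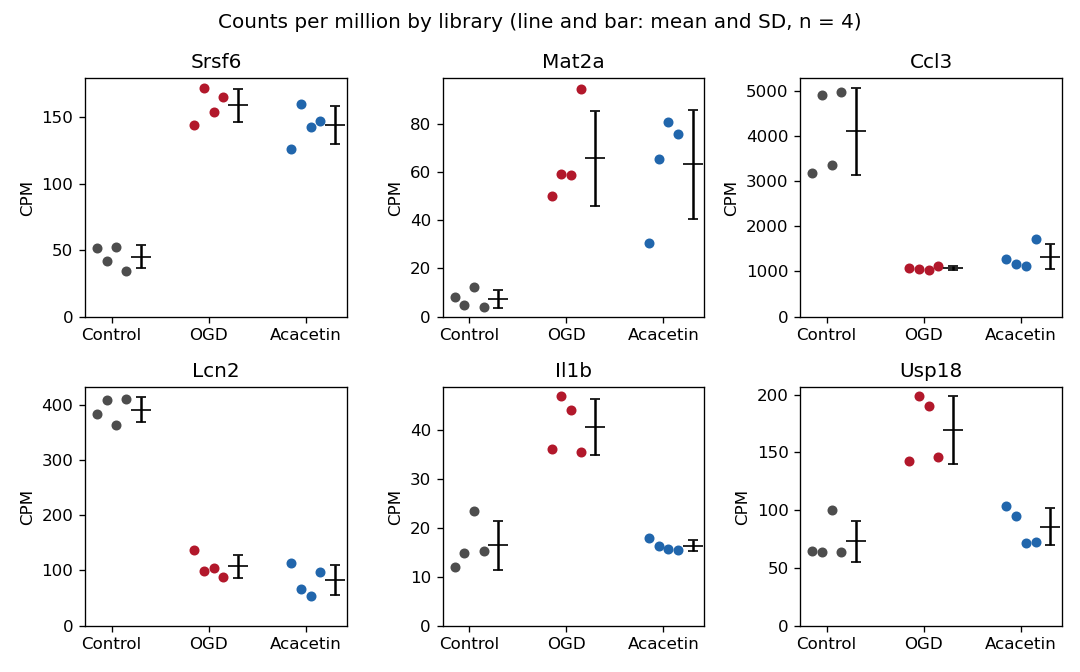
Points give the CPM of 6 genes in each library by group, with a line at the mean and a bar of SD (n = 4). Srsf6 and Mat2a were higher and Ccl3 and Lcn2 lower in OGD and in Acacetin than in Control, while Il1b and Usp18 averaged 40.6 and 169 CPM in OGD and 16.3 and 85.6 CPM in Acacetin.

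Acacetin against OGD asked which of these genes moved when acacetin was added. The smallest p-values belonged to Il1b, Id3 and interferon-inducible genes, although edgeR called none of them singly. Il1b averaged 40.6 ± 5.73 CPM in OGD and 16.3 ± 1.07 CPM in Acacetin, with a log2 fold change of -1.32 ± 0.19 and an adjusted p of 0.0686. Interferon response genes had a mean log2 fold change of -0.59 and were lower in 27 of 31. The ubiquitin-like modifier gene Isg15 (chromosome 4), chosen after its values were seen, averaged 42.3 CPM in Control, 104 CPM in OGD and 41.7 CPM in Acacetin. Mat2a averaged 65.6 ± 19.6 CPM in OGD and 63.1 ± 22.8 CPM in Acacetin, Srsf6 159 ± 12.5 and 144 ± 14.0 CPM, and Ccl3 1073 ± 39.3 and 1323 ± 277 CPM.

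EdgeR called 0 of 13249 genes in Acacetin against OGD. At an unadjusted p under 0.05 there were 685 genes where chance gives 662, and the smallest adjusted p was 0.0686. The groups did not overlap in 2.35% of genes, below the 2.86% that chance gives. DESeq2 called 37 genes, 3 higher and 34 lower, and limma on FPKM called 0. EdgeR called 9 genes without Acacetin 1, 3 without Control 3 and 1 without Control 1. In simulated data edgeR recovered 40% of 2-fold and 86% of 3-fold changes in this comparison. Changes of 2-fold or less were therefore mostly not detectable with these libraries. The simulated data held 50 changed genes per size, which makes an adjusted p easier to pass than where few genes change. The shares recovered may therefore be too high for this comparison, and larger changes could also be missed. Apol9a, with a log2 fold change of -1.84, was not called by edgeR (adjusted p = 0.0686).

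Il1b had an adjusted p of 0.0131 without Acacetin 1, 0.0248 with the length trend removed, 0.00606 with no filter on low counts and 1.02e-06 by DESeq2. For every gene, Il1b included, the adjusted p by edgeR was at least 0.327 without OGD 2 and 0.4077 without OGD 3. It was at least 0.469 without Acacetin 4 and 0.9996 with OGD 2 and 3 left out. Other genes with small p, chosen after their values were seen, were lower in Acacetin. Id3 (ENSMUSG00000007872.4, chromosome 4), an inhibitor of helix-loop-helix factors, averaged 47.0 ± 11 CPM in OGD and 18.7 ± 4.88 CPM in Acacetin. Its log2 fold change was -1.33 ± 0.20, with an adjusted p of 0.0686. That was 0.0104 with the length trend removed and at least 0.327 without OGD 2. Apol9a had -1.84 (adjusted p = 0.0686), Isg15 -1.31 (0.128), the exonuclease gene Isg20 -1.10 (0.136), Parp12 -0.75 (0.163), Xaf1 -0.96 (0.165) and Usp18 -0.98 (0.182). DESeq2 called Il1b, Id3, Apol9a, Isg20, Isg15, Irf7 and Usp18 among its 34 falls. The metallothionein gene Mt1 was among its 3 rises, with a log2 fold change of 0.70.

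The other genes fixed in advance were not called. Tnf averaged 452 ± 50.4 CPM in OGD and 454 ± 108 CPM in Acacetin (log2 fold change 0.01, adjusted p = 0.994), and its sign turned without OGD 4 (-0.06), Acacetin 1 (-0.14) or Acacetin 2 (-0.01). Ccl2 had 0.16 (adjusted p = 0.897), Ptgs2 0.88 (0.83), Hmox1 0.25 (0.842) and Vegfa 0.15 (0.902). Nos2 averaged 79.2 ± 33.7 and 63.5 ± 20.6 CPM, with -0.32 on counts (adjusted p = 0.862) and 0.00 on FPKM. On FPKM with 1 added the median of all genes lay at 0.16 in this comparison. Il6 had -0.00 on counts and 0.13 on FPKM, and Arg1 had 0.36, or -0.01 without OGD 2, -0.04 without Acacetin 1 and 2.09 without OGD 1. In the inflammatory list the smallest p after Il1b belonged to Icam1 (ENSMUSG00000037405.9, chromosome 9), with -0.40 ± 0.12 (adjusted p = 0.733), and to Traf1 (ENSMUSG00000026875.15, chromosome 2), a receptor adaptor gene, with -0.39 ± 0.16. In the hypoxia list they belonged to Egln3 (ENSMUSG00000035105.6, chromosome 12), an oxygen-sensing hydroxylase gene, with 0.49 ± 0.22, to the mitophagy gene Bnip3 (ENSMUSG00000078566.9, chromosome 7), with 0.77 ± 0.35, and to Pfkfb4 (ENSMUSG00000025648.19, chromosome 9), a regulator of glycolysis, with -0.26 ± 0.14 on counts and 0.01 on FPKM.

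Camera called 11 lists in Acacetin against OGD, 3 higher and 8 lower, each with 0 genes called over all genes. Interferon response was the strongest, with an adjusted p of 4.35e-19 and 14 genes lower when adjusted over the list alone. Antigen presentation genes had a mean of -0.30, were lower in 12 of 16 and gave 2 falls adjusted over the list alone, H2-Aa (-1.26) and the peptide transporter gene Tap1 (-0.60), with an adjusted p of 3.56e-06. Interferon had adjusted p = 0.0393 with an estimated correlation, the only list called that way, and antigen presentation 0.145. With the length trend removed as well these were 0.0579 and 0.0760, so that call was lost. Fry called the interferon and antigen presentation lists, each at 0.0113. By the exact permutation test on list means per library, with 4 against 4, the two-sided p was 0.0571 for interferon and 0.0286 for antigen presentation, and both were 0.314 after adjustment over the lists.

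The list of replication-dependent histones and other RNAs without poly(A) tails was lower in 23 of 23 genes, with a mean of -1.36 and an adjusted p of 2.94e-11 (adjusted p = 0.280 with an estimated correlation). Without OGD 2 and 3, the libraries rich in 18S rRNA, its mean was 0.07 with an adjusted p of 0.778. Complement genes were lower in 7 of 9, among them C1qa and C1qb, with a mean of -0.36 and an adjusted p of 0.0293 (0.231 with an estimated correlation). That call was lost without OGD 2 (0.0604), OGD 4 (0.0947), Acacetin 1 (0.0678), Acacetin 2 (0.0562) or Acacetin 3 (0.0626), and with a mean of at least 1 CPM (-0.23, 0.0954).

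The remaining 4 lower lists changed sign on FPKM. There the median of all genes lay at 0.16 with 1 added and at 0.24 with 0.1 added. Immediate early genes such as Fos (-0.48) and Dusp1 (-0.42) had a mean of -0.22 on counts and 0.06 on FPKM, or -0.10 relative to the median, with an adjusted p of 0.00113 (0.307 with an estimated correlation). Inflammatory NF-kB genes had -0.13 on counts and 0.09 on FPKM, or -0.06 relative to the median, were lower in 18 of 27 and gave 1 fall, Il1b, adjusted over the list alone. Their adjusted p was 0.0206 (0.307 with an estimated correlation) and was 0.0852 without OGD 1, 0.0661 without OGD 4, 0.15 without Acacetin 2 and 0.0626 without Acacetin 3, and 0.0909 with a mean of -0.08 when the length trend was removed. Myeloid identity genes such as Csf1r (-0.52) and Fcgr1 (-0.65) had -0.13 on counts and 0.08 on FPKM, or -0.08 relative to the median, with 3 falls adjusted over the list alone and an adjusted p of 0.0179 (0.280 with an estimated correlation). Their mean was -0.03 (adjusted p = 0.234) without OGD 2 and 3, the libraries rich in 18S rRNA, and -0.16 (0.0534) without Acacetin 1 and 3. DNA replication genes had a median of -0.15 and a mean of -0.03, or 0.15 on FPKM (-0.01 relative to the median, adjusted p = 0.692), 0.01 with the size factors of DESeq2 and 0.03 with rRNA genes and Lars2 left out, with an adjusted p of 0.0276 (0.491 with an estimated correlation). Without OGD 2 that adjusted p was 0.207 and the mean 0.01, without OGD 3 0.0621 and 0.03, and the call was also lost without OGD 4 (0.0562), without Acacetin 1 (0.219) and without Acacetin 1 and 3 (0.296).

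The lists higher in Acacetin than in OGD were the mitochondrially encoded, cholesterol synthesis and hypoxia genes. Mitochondrial transcripts, which encode respiratory chain subunits, were higher in 12 of 13, with a mean of 0.44 and an adjusted p of 3.56e-06 (0.231 with an estimated correlation). The gene mt-Nd4 was the only rise adjusted over the list alone, from 192 to 362 CPM. Acacetin 3 stood at 587 CPM and the other Acacetin libraries at 243 to 334 CPM. By the exact permutation test on list means the p was 0.0857 for the mitochondrial and for the cholesterol list. Both were 0.314 after adjustment over the lists, and the groups overlapped. Leaving out Acacetin 1 and 3 with OGD 4, the libraries with the steepest length slopes, brought the mean of the mitochondrial list to 0.09. Its camera adjusted p was then 0.333, while removing the length trend left 0.58 and 8.02e-06. Cholesterol synthesis genes were higher in 20 of 22, among them Hmgcs1 (0.55), with a mean of 0.25 and an adjusted p of 0.00125 (0.231 with an estimated correlation), and Acacetin 1 (mean log2 CPM 4.00) lay inside the OGD range of 3.96 to 4.14. Hypoxia genes were higher in 15 of 21, with a mean of 0.19 and an adjusted p of 0.0276 (0.561 with an estimated correlation), and an exact permutation p of 0.314. Without OGD 2 and 3 the mean was 0.07 (adjusted p = 0.910), without OGD 2 0.13 (0.207), without OGD 3 0.19 (0.124), without Acacetin 1 0.14 (0.214), without Acacetin 4 0.10 (0.399) and on FPKM with 1 added 0.34 (0.0522).

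**Figure D3:**
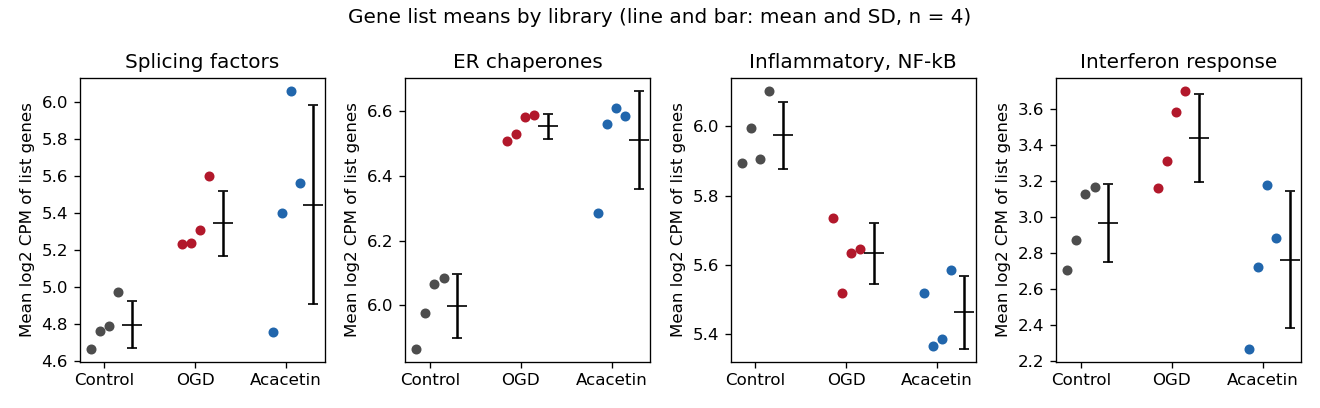
Points give the mean log2 CPM of the genes of 4 lists in each library by group, with the mean and SD (n = 4). The OGD libraries lay between 3.16 and 3.70 on the interferon list and the Acacetin libraries between 2.27 and 3.18, while splicing and chaperone lists stayed apart from Control in OGD.

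Whether acacetin moved OGD genes back was asked gene by gene. The number called in OGD against Control and called the opposite way in Acacetin against OGD was 0 by edgeR. For independent lists 0 were expected, since edgeR called 0 genes in the latter comparison. Data simulated with no effect also gave 0, where few genes are called at all, so neither 0 is informative. Il1b and Apol9a came nearest, rising by 1.31 and 3.30 on the log2 scale with OGD and standing at -1.32 and -1.84 with acacetin. DESeq2 gave 21 such genes, and edgeR gave 4 without Acacetin 1, 3 without Control 3 and 1 without Control 1. Across genes, which are not independent replicates, the fold changes of the 2 comparisons had a correlation of -0.348, where simulated data with the shared OGD libraries and no effect gave -0.515. With different OGD libraries in each comparison the correlation averaged -0.139 over 6 splits, from -0.358 to 0.0183. The covariance was -0.0816 against -0.0573 simulated, a difference of -0.0243. The simulated genes were drawn independently, without trends shared between libraries such as the length trend. The difference can therefore not be read as opposite movement due to acacetin. With the OGD libraries split the covariance ran from -0.0853 to 0.00627.

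Acacetin against Control asked how far cells given acacetin after OGD lay from Control cells. Mat2a averaged 63.1 ± 22.8 CPM (log2 fold change 3.10 ± 0.37, adjusted p = 0.000196), Srsf6 144 ± 14.0 CPM (1.68 ± 0.15, adjusted p = 5.59e-05), and Lcn2 82.3 ± 27.1 CPM (-2.25 ± 0.22, adjusted p = 7.27e-05). Il1b averaged 16.3 ± 1.07 CPM in Acacetin and 16.4 ± 4.95 CPM in Control, with an adjusted p of 0.983. Its log2 fold change was -0.01 on counts, 0.12 with the length trend removed and 0.15 on FPKM.

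EdgeR called 3559 genes, 1850 higher and 1709 lower, and 9690 were not called. The groups did not overlap in 25.7% of genes, where chance gives 2.86%. At least 2-fold changes numbered 676 higher and 765 lower. Protein-coding genes gave 1664 rises and 1572 falls, and lncRNA genes 146 and 100. The shares called were 28.2% and 23.7%, and 26.9% of all tested genes. Without Control 2 there were 2369 calls, 2363 of them among the 3559, and without Acacetin 1, the library with the lowest length slope, there were 5801, including 3440 of them. The median of all genes lay at 0.17 on FPKM with 0.1 added, at 0.13 with no filter on low counts and at 0.11 with rRNA genes left out.

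Called in both comparisons with Control were 1530 rises and 1344 falls, and 0 genes were called in opposite directions. Independent lists of these sizes would share 300 and 215. Simulated data with shared Control libraries and no effect gave 0, but without an effect few genes are called at all. That 0 therefore does not show how much the shared libraries add to the overlap. With different Control libraries in each comparison the shared rises were 519 to 722, where 59.2 to 88.4 were expected, and the shared falls 607 to 657, where 63.5 to 77.5 were expected. Mat2a, Srsf6 and Myd88 were among the shared rises and Tox2, Ccl3 and Lcn2 among the shared falls. The covariance of the fold changes was 0.389, against 0.0549 simulated from the shared libraries alone, a difference of 0.334. That simulation held no trends shared between libraries, so not all of the difference need be a shared effect. With different Control libraries in each comparison the covariance ran from 0.336 to 0.381. The correlation across genes was 0.871, against 0.50 simulated.

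The largest rises named by the rule in Acacetin against Control were in Slc18a1 (3.33 ± 0.40 on the log2 scale, adjusted p = 0.000196), Mat2a, Ppp1r10 (ENSMUSG00000039220.17, chromosome 17), Tssk6 (2.47), Tlr7 (ENSMUSG00000044583.14, chromosome X) and Nqo1 (2.18). Ppp1r10, a regulatory subunit gene of protein phosphatase 1, rose by 2.50 ± 0.33 from 6.36 ± 3.58 to 35.9 ± 4.26 CPM. The RNA sensor gene Tlr7 had 2.26 ± 0.54 and an uneven 8.26 ± 6.87 CPM in Acacetin (adjusted p = 0.00762, and 0.0501 with limma on FPKM). Tox2 (-3.46 ± 0.38), Cbr2 (-3.05 ± 0.33) and Ecel1 (-2.64) were the largest falls named by the rule. Hmcn2 (ENSMUSG00000055632.19, chromosome 2), an extracellular matrix gene, fell by 2.63 on the log2 scale, and Haao (ENSMUSG00000000673.10, chromosome 17), an enzyme gene of tryptophan breakdown, by 2.59. Ddit3 (ENSMUSG00000025408.16, chromosome 10), the stress transcription factor CHOP, went from 60.2 ± 24.4 to 9.88 ± 2.22 CPM.

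The inflammatory NF-kB list was lower in Acacetin than in Control, with 2 rises and 9 falls among 27 genes (3 and 9 adjusted over the list alone), a mean of -0.47 and an adjusted p of 0.00457 (0.399 with an estimated correlation). Lcn2 and Ccl3 (-1.64 ± 0.20) fell, and Cxcl10 (-1.39), an interferon-induced chemokine gene, and Relb (-0.92) were also lower, while Nfkbid rose by 1.18 ± 0.18. Nos2 had -1.60 ± 0.29 and an adjusted p of 0.00160. Tnf had -0.38 (adjusted p = 0.110), or 0.0420 by DESeq2 and 0.0134 by edgeR without Acacetin 1. Ccl2 had -0.40 (adjusted p = 0.0930), or 0.0268 by DESeq2. Ptgs2 had -0.83 (adjusted p = 0.253), and -1.52 with 0.0301 without Acacetin 3. Il6 had 0.14 (adjusted p = 0.766), or -0.12 without Acacetin 3, Arg1 -0.78 (0.468), Vegfa 0.22 (0.302) and Hmox1 -0.16 (0.572).

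Antigen presentation genes gave 1 rise and 6 falls among 16 (1 and 7 adjusted over the list alone), with a mean of -0.45 and an adjusted p of 0.00585 (0.399 with an estimated correlation). The MHC class II gene H2-Aa (ENSMUSG00000036594.16, chromosome 17) went from 1.75 ± 0.302 to 0.369 ± 0.0418 CPM (adjusted p = 0.000209). Tap1 (ENSMUSG00000037321.18, chromosome 17) had -0.92 and the immunoproteasome gene Psmb9 (ENSMUSG00000096727.4, chromosome 17) -0.87, while the transactivator gene Nlrc5 rose by 0.82. Interferon response genes were not separated from other genes, with 1 rise and 5 falls among 31, a mean of -0.10 and a camera adjusted p of 0.355. Oas2 rose by 1.17, and Rsad2 (-1.43), Ifi27l2a (-1.32) and Irf7 (-0.73) were among the falls. Without Control 4 the list mean was 0.04.

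Mitochondrially encoded genes gave 6 rises among 13 (7 adjusted over the list alone), with a mean of 0.98 and an adjusted p of 0.00141 (0.399 with an estimated correlation). The complex I gene mt-Nd2 (ENSMUSG00000064345.1) averaged 142 ± 47.1 CPM in Control, 316 ± 24.3 CPM in OGD and 510 ± 110 CPM in Acacetin. Its log2 fold change against Control was 1.84 ± 0.23, that of mt-Nd1 (ENSMUSG00000064341.1) 1.89 ± 0.25 and that of mt-Nd4 (ENSMUSG00000064363.1) 1.51. In OGD against Control the list had 3 rises among 13 and a camera adjusted p of 0.157.

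Camera called 13 lists in Acacetin against Control, 9 higher and 4 lower, and 0 with an estimated correlation, while fry called 15. Splicing gave 19 rises and 1 fall among 40 (25 and 1 adjusted over the list alone, adjusted p = 6.30e-06, 0.399 with an estimated correlation), with Srsf2 at 0.95 and Srsf3 at 1.31. Endoplasmic reticulum chaperones gave 8 rises among 18 (9 adjusted over the list alone, adjusted p = 0.000731, 0.274 with an estimated correlation), with Dnajb11 at 1.10, Syvn1 at 0.87 and Hyou1 at 0.75. Ribosome biogenesis gave 11 rises and 1 fall among 22 (14 and 1 adjusted over the list alone, adjusted p = 0.00136, 0.399 with an estimated correlation), with Rrs1 at 0.95, Polr1b at 0.78 and Nop2 at 0.64. DNA replication gave 10 rises and 1 fall among 23 (11 and 1 adjusted over the list alone, adjusted p = 0.00585, 0.399 with an estimated correlation), with Fen1 at 1.21, Rrm2 at 0.89 and the cyclin gene Ccne1 (ENSMUSG00000002068.17, chromosome 7) at 0.65.

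Toll-like receptor signalling gave 6 rises and 1 fall among 17 (8 and 1 adjusted over the list alone, adjusted p = 0.00672, 0.399 with an estimated correlation), with Myd88 at 1.36, Tirap at 1.28 and Tlr2 at 0.86. Heat shock genes gave 5 rises among 14 (7 adjusted over the list alone, adjusted p = 0.0124, 0.399 with an estimated correlation). Hsph1 (ENSMUSG00000029657.16, chromosome 5) had 1.17 ± 0.30 (adjusted p = 0.0112, and 0.0845 with limma on FPKM). Dnaja1 had 1.11 (0.0154, and 0.0506 without Control 1 and 0.0762 with limma on FPKM), and Hspa8 had 0.55 (0.0291, and 0.0871 without Control 1, 0.0894 without Control 2, 0.0867 without Acacetin 2 and 0.0615 without Acacetin 4). Mitosis genes gave 6 rises among 22 (8 adjusted over the list alone, adjusted p = 0.0165, 0.399 with an estimated correlation), and without Acacetin 3 their mean went from 0.74 to 0.28 (adjusted p = 0.116). NRF2 genes gave 9 rises among 21 (9 and 1 fall adjusted over the list alone, adjusted p = 0.0382, 0.731 with an estimated correlation), with Nqo1 and the glutathione synthesis gene Gclc (1.74) among them, and an adjusted p of 0.225 without Acacetin 1, 0.0688 without Acacetin 2, 0.0501 with a mean of at least 1 CPM and 0.0556 without Acacetin 1 and 3, while the mean of 0.47 stayed between 0.39 and 0.50.

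Ribosomal protein genes were lower in 25 of 25, with a mean of -0.41, 0 called singly and an adjusted p of 0.000731 (0.731 with an estimated correlation). Nuclear genes of oxidative phosphorylation were lower in 28 of 31, with a mean of -0.23, 0 called singly and an adjusted p of 0.0124 (0.83 with an estimated correlation). Their mean was -0.16 (adjusted p = 0.0525) with the length trend removed and -0.13 (0.147) without Acacetin 3. Hypoxia genes had 2 rises and 4 falls among 21 (3 and 4 adjusted over the list alone), a median of 0.22, a mean of 0.00 that was -0.03 with the length trend removed, and a camera adjusted p of 0.977. Ak4 rose by 0.98, the oxygen-sensing hydroxylase gene Egln1 (ENSMUSG00000031987.7, chromosome 8) by 0.74 ± 0.18 (adjusted p = 0.00983), and Car9 fell by 1.81 on the log2 scale.

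On 7 of the 13 called lists the Acacetin and Control libraries overlapped because of Acacetin 1. Its mean log2 CPM lay inside the Control range for splicing (4.75, with Control at 4.67 to 4.97 and the other Acacetin libraries at 5.402 to 6.059) and ribosome biogenesis (5.65, with 5.62 to 5.74 and 6.28 to 6.67). The same held for Toll-like receptor signalling (2.72, with 2.45 to 2.76 and 3.34 to 3.68) and heat shock (5.78, with 5.50 to 5.86 and 6.33 to 6.67), where Hsph1 at 15.5 CPM and Dnaja1 at 10.3 CPM also lay inside it. It lay below every Control library for mitosis (4.21, with 4.36 to 4.63 and 4.90 to 5.79), and above every one for ribosomal proteins (11.761, with 11.536 to 11.752 and 10.786 to 11.250) and nuclear oxidative phosphorylation (8.48, with 8.20 to 8.37 and 7.71 to 8.09). The exact permutation p (two-sided, n = 4) was 0.114 for splicing, 0.0857 for ribosome biogenesis, 0.0571 for Toll-like receptor signalling and for heat shock, 0.200 for mitosis, 0.143 for ribosomal proteins and 0.171 for oxidative phosphorylation. The other 6 lists had no overlap between the groups and the smallest possible p of 0.0286 (0.105 after adjustment over the lists), although Acacetin 1 was also nearest to Control on the endoplasmic reticulum chaperone list (6.285, with the others at 6.559 to 6.609).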

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

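Both tests of the 18S rRNA and Lars2 pattern described here were chosen only after the result was seen. The groups of 4 libraries were searched for a single library whose gap to the nearest of the others took up nearly the whole range of its group (Dixon's test at the 95% level). This picked out 17 of 228 groups, where chance picks out about 1 in 20, which is 11.4 of them.

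In Control, Usp18, the gene of an enzyme that removes ISG15, stood at 99.7 CPM in Control 3 and between 63.8 and 65.0 CPM in the other libraries. The chaperone genes Dnajb11 (50.9 CPM against 42.0 to 43.3 CPM) and Hyou1 (108 CPM against 104 CPM in each of the others) were also highest in Control 3. Il6 stood at 2.55 CPM in Control 4, with the others between 1.92 and 1.99 CPM, and the small nucleolar RNA Snora73b at 1.20 CPM in Control 2, with the others between 0.573 and 0.674 CPM. Ribosomal protein genes took 20.1% of the reads of Control 4 and 21.3% to 21.5% elsewhere in the group. Mitochondrial genes took 0.377% of the reads of Control 2 and 0.490% to 0.514% elsewhere.

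In OGD, Arg1, the arginase gene, stood at 3.92 CPM in OGD 1 and between 0.0999 and 0.552 CPM in the others, and without OGD 1 its log2 fold change against Control was -2.87. Slc18a1 stood at 1.80 CPM in OGD 1, below the 3.51 to 3.75 CPM of the others, and Hmcn2 at 6.13 CPM, above their 4.50 to 4.69 CPM. Nfkbid, the NF-kB inhibitor gene, was at 82.6 CPM in OGD 2 and 68.1 to 69.8 CPM in the others, and mitochondrial genes took 0.486% of the reads of OGD 2 against 0.555% to 0.566%. In OGD 4 Vegfa stood at 17.8 CPM (others 15 to 15.5 CPM) and the immunoproteasome gene Psmb9 at 36.3 CPM (others 51.9 to 54.2 CPM). In Acacetin, Polr1b stood at 112 CPM in Acacetin 2 against 81.4 to 85.3 CPM, and Srxn1 at 76.2 CPM against 49.3 to 52.4 CPM.

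Lars2, the gene of the mitochondrial leucyl-tRNA synthetase, stood at 1632 CPM of all reads in Control 2 and 114 to 304 CPM in the other Control libraries, and reached 7369 and 12668 CPM of all reads in OGD 2 and OGD 3, the libraries with 13.1% and 21.3% 18S rRNA. Over the other 10 libraries log2 Lars2 followed log2 18S rRNA, with Pearson's r = 0.992 (permutation p of 1e-05, the smallest that 100000 resamplings can give) and Spearman's rho = 0.964 (permutation p of 3e-05). Without the 2 libraries farthest from the median r was 0.989, and it was 0.992 within groups, so reads of ribosomal RNA counted in Lars2 are a candidate source of its level. In OGD 2 and OGD 3 together, 65.2% of the 23 tested genes of the histone list lay above all other 10 libraries, where chance gives 1.52% and all tested genes gave 5.47%, and Rmrp, a small RNA without a poly(A) tail, reached 143 and 298 CPM with TMM-scaled library sizes against at most 11.8 CPM elsewhere. This is what carry-over of RNA without poly(A) tails would give, and no biological explanation was tested.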

How the results depend on the processing

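Settings chosen only after the data were seen were the length trend removed, rRNA genes and Lars2 left out, OGD 2 and 3 left out, Acacetin 1 and 3 left out, Acacetin 1 and 3 with OGD 4 left out, and each library of the group outside the comparison left out. So were FPKM, no filter and thinned counts where they are used for named genes, and FPKM for lists. For lists the direction was read from the mean log2 fold change, a choice made after first values were seen that counts more values as reversed. Where no reason is given below, the cause was not tested.

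Srsf6, Mat2a, Ccl3, Lcn2 and most other genes named kept their direction and call. Of 2551 alternative values for 116 named results, 2436 kept both, 42 lost the call, 27 gained one and 46 changed sign, and 87 of the 116 kept both under every alternative run. In OGD against Control 7 named calls were lost with OGD 2 and 3 left out. Whether this came from fewer libraries or from these libraries in particular was not tested. Over all comparisons 8 named calls were lost on FPKM with 1 added. For lists 624 of 720 alternative values kept direction and call, 73 lost the call and 23 changed sign.

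The count of genes in OGD against Control was 3813 and became 2024 with OGD 2 and 3 left out. Whether that drop came from fewer samples or from these libraries in particular was not tested. With Acacetin 1 and 3 left out the count was 5001, and with Acacetin 1, 3 and OGD 4 left out it was 5405. The count was 1532 with an absolute log2 fold change of at least 1 (a stricter limit). Without 1 library it ran from 2794 to 4660. In Acacetin against Control it was 3559, became 1441 with the same limit, and ran from 2369 without Control 2 to 5801 without Acacetin 1. In Acacetin against OGD the count of 0 became 37 with DESeq2, 8 with no filter on low counts, 2 with the replicate block (Il1b and Id3, each at 0.0447), 4 with the length trend removed, 4 with Acacetin 1 and 3 left out and 16 with Acacetin 1, 3 and OGD 4 left out, and ran from 0 to 9 without 1 library. Genes moved back by acacetin went from 0 to 21 with DESeq2 (Il1b and Apol9a were lower in Acacetin in its calls), 5 with no filter, 1 with the block, 3 with the length trend removed, 1 with Acacetin 1 and 3 left out and 5 with Acacetin 1, 3 and OGD 4 left out, and ran from 0 to 4 without 1 library.

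The replicate numbers were not used as pairs. Some samples matched best with their own number and some did not, so the block is given only as an alternative. Replicate 4 matched its own number best in each comparison, with correlations across genes of 0.506, 0.380 and 0.402. Replicate 3 did so in none (0.0708, -0.118 and -0.291). A shared origin behind the numbers is therefore neither shown nor excluded. It called 4572, 2 and 4279 genes in OGD against Control, Acacetin against OGD and Acacetin against Control.

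Called lists in OGD against Control went from 8 to 0 with an estimated correlation and 15 with fry, in Acacetin against OGD from 11 to 1 and 2, and in Acacetin against Control from 13 to 0 with an estimated correlation. Without 1 library they ran from 7 to 10, 9 to 15 and 11 to 13. The estimated correlation between genes, above the preset 0.01 in each called list, widens the test. The opposite movement of OGD and Acacetin fold changes, -0.139 on average, was -0.315 with OGD 1 and 2 against Control, -0.358 with OGD 1 and 3 and 0.0183 with OGD 3 and 4.

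Most signs that reversed belonged to values near 0. Values on FPKM are given with 1 and with 0.1 added. Il6 in OGD against Control (0.15) was at -0.0774 with OGD 2 and 3 left out, -0.00386 and -0.0142 on FPKM, and from -0.0399 (without OGD 2) to 0.24 without 1 library. Il6 in Acacetin against OGD (-0.00) was at 0.060 with DESeq2, 0.0544 with its size factors, 0.0828 with only the 8 libraries, 0.142 with the length trend removed, 0.0832 with rRNA genes left out, 0.302 with OGD 2 and 3 left out, 0.0295 with Acacetin 1 and 3 left out, 0.0694 with no filter and 0.127 and 0.172 on FPKM, and from -0.265 (without Acacetin 3) to 0.238 (without Acacetin 1). Tnf in Acacetin against OGD (0.01) was at -0.00459 with the block, -0.00896 with thinned counts and -0.0677 with Acacetin 1, 3 and OGD 4 left out, and from -0.14 (without Acacetin 1) to 0.137 (without Acacetin 3). Arg1 (0.36) was at -0.321 with OGD 2 and 3 left out and -0.056 with Acacetin 1, 3 and OGD 4 left out, and from -0.0409 (without Acacetin 1) to 2.09 (without OGD 1). On FPKM, Vegfa in OGD against Control (0.08) was at -0.0409 and -0.0618, and from 0.00453 to 0.148 without 1 library. In Acacetin against OGD, Pfkfb4 (-0.26) was at 0.0132 and 0.0276 on FPKM, and from -0.312 to -0.21 without 1 library, and Nos2 (-0.32) at 0.00188 and 0.0148, and from -0.522 to -0.067. The median of all genes on FPKM lay at 0.16 and 0.24 in that comparison. Pfkfb4 and Nos2 stayed below it, so a shift of scale is part of their change of sign.

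Il1b in Acacetin against Control (-0.01) was at 0.0262 with the block, 0.118 with the length trend removed, 0.0149 with rRNA genes left out, 0.0429 with OGD 2 and 3 left out, 0.0159 with no filter, 0.073 with thinned counts and 0.151 and 0.173 on FPKM, and from -0.128 (without Control 1) to 0.219 (without Control 3). Il6 in that comparison (0.14) ran from -0.119 (without Acacetin 3) to 0.384 (without Acacetin 1). The mean of the DNA replication list in Acacetin against OGD (-0.03) was 0.0128 with the size factors of DESeq2, 0.0344 with only the 8 libraries, 0.0322 with rRNA genes left out, 0.0854 with OGD 2 and 3 left out and 0.151 and 0.192 on FPKM, and from -0.0955 (without Acacetin 3) to 0.0342 (without OGD 3). On FPKM the means of 3 more lists turned in that comparison, where the median of all genes lay at 0.16 and 0.24, so a shift of scale is part of it. The inflammatory list (-0.13) was at 0.0942 and 0.116 (without 1 library -0.183 to -0.0779), the immediate early list (-0.22) at 0.0581 and 0.069 (-0.293 to -0.166) and the myeloid list (-0.13) at 0.0763 and 0.105 (-0.161 to -0.0577). The histone list (-1.36) was at 0.0692 with OGD 2 and 3 left out, the libraries that held its high values. The hypoxia list in Acacetin against Control (0.00) was at -0.00601 with a mean of at least 1 CPM, -0.0406 with the block and -0.0314 with the length trend removed, and from -0.0923 (without Acacetin 4) to 0.0818 (without Control 4). The interferon list in that comparison (-0.10) ran from -0.303 (without Acacetin 3) to 0.0442 (without Control 4).

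Counts thinned to the smallest library of 16427886 reads gave 3608, 0 and 3317 genes, so unequal depth changed these counts little. Genes at the lowest CPM rest on few reads per library. Examples are Arg1 in OGD 2, 3 and 4 (0.0999 to 0.552 CPM), Tssk6 in Control (0.166 to 0.674 CPM) and H2-Aa in Acacetin (0.320 to 0.420 CPM). The Arg1 fold change without OGD 1 depends on such values. Il6, at 2.10 to 2.34 CPM on average in Control and OGD, was also low but lay above them.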

Other observations

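The tests of the gene length trend and of the libraries rich in 18S rRNA given below were chosen only after the results were seen. Some receptor genes, chosen here after their values were seen, were called in OGD against Control, while the homeostatic microglia list had 1 rise and 1 fall among 10 and a camera adjusted p of 0.530. Csf1r (ENSMUSG00000024621.17, chromosome 18), the receptor that microglia need for survival, rose from 66.3 ± 8.43 to 144 ± 12 CPM (log2 fold change 1.12 ± 0.14, adjusted p = 0.000170 by edgeR, n = 4), and by 0.60 in Acacetin against Control (adjusted p = 0.00662). The complement receptor genes C5ar1 (30.2 to 78.5 CPM) and C3ar1 (14.7 to 43.6 CPM) rose by 1.38 ± 0.14 and 1.57 ± 0.22 on the log2 scale. The fractalkine receptor gene Cx3cr1 went from 4.39 to 2.10 CPM (-1.07 ± 0.24). Fosl1, an AP-1 subunit gene, rose from 13.1 to 38.5 CPM (1.56 ± 0.14, adjusted p = 2.64e-05).

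Autophagy and lysosome genes had 0 rises and 5 falls among 20 in OGD against Control, the largest in Wipi1 (-1.80 ± 0.32), which marks forming autophagosomes, and the initiating kinase gene Ulk1 (-0.91). The camera adjusted p of this list was 0.172. Apoptosis genes had 5 rises and 0 falls among 19, with the death-promoting genes Bid at 1.45 ± 0.14 and Bcl2l11 at 0.89 ± 0.12, and a camera adjusted p of 0.179. P53 targets had 1 rise, Aen (1.33 ± 0.18), and 4 falls among 15, such as Plk2 (-1.52), with 0.312. Of 26 lncRNA genes listed in advance 7 rose and 2 fell, among them the small nucleolar RNA host genes Snhg15 (27.9 to 78.4 CPM) and Zfas1 (91.3 to 50.3 CPM), with 0.199. Of all tested genes 28.8% were called in OGD against Control, so the numbers called do not by themselves set these lists apart. Markers of 6 other cell types had medians of at most 0.275 CPM, but the single genes Cnp, Flt1 and Lck averaged 87.2, 26.8 and 11.2 CPM over all libraries.

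The higher splicing, chaperone, replication, ribosome biogenesis, interferon and Toll-like receptor lists and the lower ribosomal protein list in OGD were set against 2 technical explanations. With the length trend removed the 8 list means kept a median of 93.9% of their size, and with OGD 2 and 3 left out 106%, and 8 of 8 lists kept their call each time, with Srsf6 and Dnajb11 among their genes. These tables argue against gene length and the 18S-rich libraries as the whole cause. A correlation between the genes of each list stays open, since 0 of the 8 were called when it was estimated, and 11 of the 35 splits of the 8 libraries called 8 lists or more, with 15 as the highest of the other splits. Chance can therefore not be excluded for the number of lists, and the effect of OGD itself stays among the open explanations.

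Interferon response genes such as Isg15, Usp18 and Rtp4 were higher in OGD than in Control and lower in Acacetin than in OGD. In OGD against Control 10 of the 31 tested were called higher and 1 lower, while 27 were lower in Acacetin than in OGD. Isg20 and Irf7, also lower in Acacetin, had log2 fold changes of only 0.08 and 0.14 in OGD against Control. Both genes were chosen after their values were seen, and edgeR called neither in Acacetin against OGD (adjusted p = 0.136 and 0.242). Their lower values were not a return from a called rise. For the list as a whole the mean in Acacetin against Control was -0.10 (camera adjusted p = 0.355), which does not show a fall below Control. With the length trend removed 93.9% of the list mean of Acacetin against OGD was left, although its adjusted p with an estimated correlation went from 0.0393 to 0.0579. Without any 1 library of the 8 at least 78.0% of the mean was left, so a single library does not account for it. In 6 of 6 splits of the OGD libraries the list rose in one part (0.27 to 0.67) and fell from the other (-0.47 to -0.88). A shift common to all OGD libraries would pass every split, so the splits cannot exclude it. A response to acacetin is a candidate explanation that stays a hypothesis, found and tested on the same data. The exact permutation p of 0.0571 (two-sided, n = 4) for its list mean, and Acacetin 3 at 3.18 against 3.16 in OGD 1, leave a difference between these samples for another reason open.

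For genes in OGD against Control, 1 of 35 splits, the real one, gave as many as 3813, and the highest other gave 0. With 35 splits the smallest two-sided p is 0.0286, so this argues against chance but cannot exclude it. Nor can it tell OGD from another difference between the groups of libraries. For Acacetin against Control 1 of 35 splits gave as many as 3559, and the highest other gave 2265 (Acacetin 1 with Control 1, 2 and 3 against the rest). The same limits hold there. In Acacetin against OGD all 35 splits gave at least the real count of 0, as any split must, so this test says nothing about chance. The split of Acacetin 1 and OGD 1, 2 and 3 against the other libraries called 5133 genes, which points to a structure among these samples other than their groups. Those libraries had length slopes of -0.264, -0.0677, -0.189 and -0.0796, and the others, OGD 4 (0.209) and Acacetin 2, 3 and 4 (0.0289, 0.398 and 0.163), had slopes above 0. Genes moved back by acacetin were at least the real 0 in 35 of 35 splits, which again says nothing, with 2863 as the highest other. The 11 lists of Acacetin against OGD were matched in 3 of 35 splits (highest other 12), and the 13 lists of Acacetin against Control in 5 of 35 (highest other 14), so chance cannot be excluded for either number.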
